A study of Rattus norvegicus with 11 samples.

How the data were processed

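Gene expression was measured in whole lung of Dahl salt-sensitive rats of 250 to 350 g on 11 Affymetrix rat arrays, each hybridised with labelled cRNA made from total RNA. The arrays belong to 3 groups: room air (normoxia, 4 arrays), hypoxia at an inspired oxygen of about 9.5% (4 arrays), and the same hypoxia with SU5416, an inhibitor of the vascular endothelial growth factor (VEGF) receptors (3 arrays). Lungs were taken after 3.5 weeks. The group given sorafenib that the study also names was not analysed here.

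The deposited values are log2 signal intensities, 1 per probe set and array, and per the labels they were summarised with RMA, for which the submitters' processing notes give no version. The distributions differ in shape between arrays, which the quantile step of RMA would have removed, and the mean of the linear values after trimming 2% from each end is 500 on every array. Scaling to a common target is the step this pattern matches, so the summarisation behind the values is uncertain, whereas the log2 scale is not. Array medians lay between 7.802 and 8.005 log2. The values were used as deposited, without further normalization.

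Of 31099 probe sets, the 57 array controls were set aside and 31042 were tested. Gene names came from the array's annotation and current Entrez gene records: 20826 probe sets name 1 gene, 436 name several and 9780 name none, for 14217 genes. The background level was the 95th percentile of 27 control probe sets for Bacillus subtilis transcripts, 5.72 log2; 18.8% of the probe sets had a mean below it. A fold against a group at background is given as a lower bound, computed from that level.

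All 11 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 8 residual degrees of freedom), from which 3 contrasts were taken: hypoxia against normoxia, hypoxia with SU5416 against normoxia, and hypoxia with SU5416 against hypoxia. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 31042 probe sets of a contrast. A probe set was called at an adjusted p below 0.05. The median standard error of a log2 difference was 0.19, 0.2 and 0.2. Changes are differences of mean log2 values, given with the standard deviation (SD) between arrays or the standard error (SE) of the difference.

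Lists of genes for pathways and cell types, 33 in all, were written before the data were examined, as were the comparisons, the alternatives unless said otherwise, and the rule for naming genes. They hold 659 symbols, of which 575 were measured. Each gene was represented by its probe set of highest mean, and each list with at least 5 measured genes was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Beside it stand camera with a correlation estimated from the arrays and fry, adjusted the same way. The rule names, per contrast, up to 8 genes that rose most and 8 that fell most among called probe sets with 1 gene symbol whose arrays did not overlap between the groups, 1 probe set per gene, the one of highest mean. It adds up to 4 members of smallest adjusted p from each list that passed or that holds a called member. It also names a fixed panel of vascular genes whatever their values, where a probe set carries the name.

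The alternatives were quantile normalization, centring on the array median, leaving out probe sets with a mean below the median of all, leaving out the 25% with the smallest interquartile range, fitting only the 2 groups compared, eBayes with trend and robust options, array quality weights, other thresholds, the replicate number as a block, and leaving out each array in turn. SAM was computed again from its definition with the delta of 0.639 and the minimum fold of 1.4 that the series text names; the study's software version is not stated there, so its counts may differ. After the data had been seen, fits without the normoxia arrays 1 and 2 and with the beta-actin gap between 3′ and 5′ probe sets as a covariate were added. The labels pair no arrays. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

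The procedure was tested on simulated data with the same groups, in which a small number of the 31042 probe sets were changed. Noise was drawn independently for each probe set, with its residual spread taken as equal on all arrays. Unequal array quality and correlation between genes are thus left out, and the rates may not hold for the real arrays. Of true changes of 2 on the log2 scale, 81.8% were called in hypoxia against normoxia, 81.8% in hypoxia with SU5416 against normoxia and 77.3% in hypoxia with SU5416 against hypoxia. Of changes of 1, 58.2%, 37.3% and 44.8% were called, and of changes of 0.5, 4.48%, 5.97% and 5.97%. False calls numbered 5 of 101, 10 of 93 and 8 of 93.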

Results

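Lung expression profiles were collected from rats kept for 3.5 weeks in room air (n = 4), in hypoxia (n = 4), or in hypoxia with the VEGF receptor inhibitor SU5416 (n = 3), a combination used to provoke pulmonary hypertension. The comparisons ask what chronic hypoxia changes in the lung and what giving SU5416 adds. No group is labelled as given SU5416 without hypoxia or its vehicle, so receptor blockade is not separated from other effects of the treatment. The number of arrays limits the precision. The labels do not state that each array comes from a different animal. The p-values treat the arrays as independent and would be too small if any share an animal.

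A common measure of RNA integrity, the gap between 3′ and 5′ probe sets of a transcript, differed within the normoxia group. The signal of the 3′ probe set of beta-actin exceeded that of the 5′ probe set by 2.24 log2 on normoxia array 1 and by 1.33 on normoxia array 2, against 0.51 to 0.87 on the other 9 arrays. The gap of Gapdh was likewise widest on these arrays (0.84 and 0.64), whereas that of hexokinase stood out on array 2 (3.22) and not on array 1 (1.82, against up to 2.44 elsewhere). The first principal component, with 31.6% of the variance, placed these arrays at −41 and −19.8 and the normoxia arrays 3 and 4 at 19.4 and 14.6. The counts without these arrays are given with the comparisons.

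**Figure D1:**
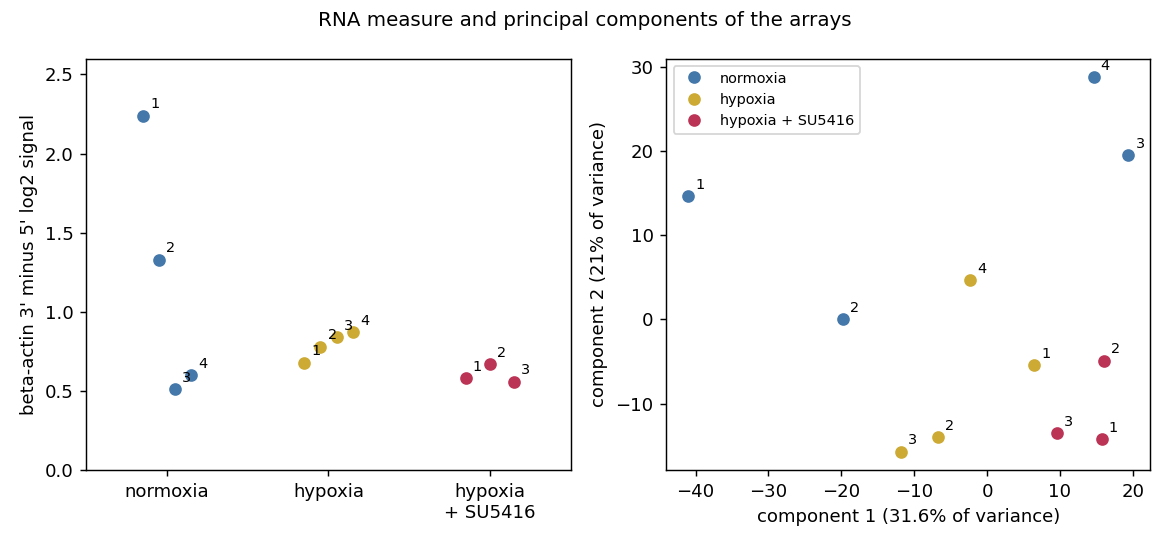
Beta-actin 3′ minus 5′ signal (log2) and position on the first principal component for each of the 11 arrays, by group. Normoxia arrays 1 and 2 have gaps of 2.24 and 1.33, above the 0.51 to 0.87 of the other 9 arrays.

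Hypoxia alone gave calls for few single genes, a number that was higher without normoxia arrays 1 and 2. As sets, genes of lymphocytes were lower and genes of cholesterol synthesis and glycolysis higher with a preset correlation. These calls were lost with adjusted p = 0.71 with an estimated correlation for T and NK cells, B and plasma cells and glycolysis, and adjusted p = 0.83 with an estimated correlation for cholesterol synthesis. Among genes of oxygen sensing, the glycolytic enzyme Pfkl stood at 10.45 ± 0.23 (SD, n = 4) against 9.37 ± 0.51 (n = 4), 2.1-fold higher, and the lactate dehydrogenase Ldha 1.29-fold higher (12.18 ± 0.07 against 11.82 ± 0.16), neither past the threshold over all probe sets (limma adjusted p = 0.249 and 0.301). Without normoxia arrays 1 and 2, a fit chosen after seeing the data, Pfkl was called (1.49), but there the beta-actin gap also separates both groups. The endothelial VEGF receptor Kdr was 1.19-fold lower and the vasoconstrictor peptide Edn1 1.23-fold higher, with limma adjusted p of 0.432 and 0.547.

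Of 31042 probe sets, 2 were called between hypoxia and normoxia (limma, 1 higher and 1 lower). An unadjusted p under 0.05 was found for 3406 probe sets, where 1552 would arise by chance, and the arrays of both groups did not overlap for 1902 (6.13%, against 2.86% by chance). Both called genes fall outside the naming rule and were chosen after their values were seen. Opcml, an adhesion molecule of neurons, was 4.5-fold lower in hypoxia (5.79 ± 0.13 against 7.96 ± 0.20, adjusted p = 0.00109), but its other probe set differed by −0.66 (adjusted p = 0.383). The transporter Slc6a17 stood higher at 7.02 ± 0.12 against a background mean of 5.69 ± 0.28 in normoxia (adjusted p = 0.0461), and its other 4 probe sets, between −0.26 and 0.44, were not called. After quantile normalization or centring on the median, 1 probe set was called, 0 higher and 1 lower.

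The count moved with the normoxia arrays. Without normoxia arrays 1 and 2, 99 probe sets were called (57 higher, 42 lower), Opcml and Slc6a17 among them. In that fit the beta-actin gap separates the groups, being 0.51 and 0.6 in normoxia and 0.68 to 0.87 in hypoxia. Without normoxia array 1 alone there were 4, and without hypoxia array 4 there were 14. The other arrays, left out one at a time, gave 1 to 3 calls. SAM was computed again with the delta and fold minimum of the series text, so it is not certain to match the study's own counts. It returned 584 probe sets, all lower, with an estimated 18.6% false. Over all probe sets, values in hypoxia were slightly lower (median difference −0.045, 42.4% of probe sets higher). With the dimmer probe sets left out the median difference was 0, so this shift lies among the dimmer ones. It was also 0 after quantile normalization, which equalises the distributions of the arrays by design. How far this shift contributes to the SAM count was not tested.

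As sets, 7 of 33 gene lists passed in hypoxia against normoxia by limma's camera, 5 up and 2 down. None of the 7 passed with an estimated correlation, and 0 passed fry, which asks whether a list's genes move on balance in a single direction. Its mixed test, which asks whether they change in either direction, was passed by 10. After quantile normalization camera with the preset correlation again passed 7 lists, 5 of them the same, but now 3 up and 4 down. T and NK cell genes were lower (median −0.40, 18 of 20 lower, camera adjusted p = 0.00039; adjusted p = 0.71 with an estimated correlation). The kinase Zap70 differed by −0.71, the adhesion receptor Cd2 by −1.06, the NK receptor Klrd1 by −0.59 and the interleukin receptor Il7r by −0.42 (SE 0.19, 0.32, 0.21 and 0.15; n = 4 and 4); none passed over all genes or adjusted over the list alone. Cardiac muscle genes were lower by as much without passing (median −0.45, 19 of 20 lower, adjusted p = 0.053; adjusted p = 0.94 with an estimated correlation). Whether this list passed depended on which array was left out. B and plasma cell genes were lower too (median −0.41, 10 of 11 lower, adjusted p = 0.0052; adjusted p = 0.71 with an estimated correlation). There, 0 members passed over all genes and 2 fell adjusted over the list alone, the B cell surface protein Ms4a1 (−0.62, SE 0.12) and the B cell scaffold Bank1 (−1.04, SE 0.23); the kinase Blk stood at −0.53 and Cd22 at −0.26.

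Cholesterol synthesis genes were higher (median 0.25, 13 of 14 higher, camera adjusted p = 0.0014; adjusted p = 0.83 with an estimated correlation), with Sqle at 0.79, Mvd at 0.42, Acat2 at 0.37 and Dhcr7 at 0.33; none passed over all genes or adjusted over the list alone. This set lost its call without normoxia array 1 and without arrays 1 and 2. HIF targets and glycolysis genes had a median of 0.13 (20 of 29 higher, adjusted p = 0.0052; adjusted p = 0.71 with an estimated correlation). Besides Pfkl, the only member to rise adjusted over the list alone, they include the mitophagy gene Bnip3 (0.75, SE 0.22) and Aldoa (0.34, SE 0.11); 0 passed over all genes. Glucocorticoid targets had a median of 0.52 (9 of 11 higher, camera adjusted p = 0.0091, and adjusted p = 0.83 with an estimated correlation). They include Errfi1 at 0.73, Cebpd at 0.68 and Sgk1 at 0.55, with 0 members past either adjustment. That call was lost without normoxia array 3 and without hypoxia array 1. Genes of mitochondrial respiration (median 0.08, 20 of 26 higher, adjusted p = 0.011) and of the extracellular matrix (median 0.09, 23 of 33 higher, adjusted p = 0.012) each had an adjusted p = 0.94 with an estimated correlation, and no member of either passed over all genes or adjusted over the list alone. The lung isoform of a cytochrome oxidase subunit, Cox4i2, differed by 0.45, Cyc1 by 0.29, Ndufv1 by 0.27 and Cox5a by −0.21; the matrix genes Col4a2, Vcan, Bgn and Tnc differed by 0.41, 0.61, 0.51 and −0.46. Both lists lost their calls after quantile normalization, without normoxia array 1, and without normoxia arrays 1 and 2. The matrix call was kept in 8 and the mitochondrial call in 12 of 15 other fits.

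The calls of the B and plasma cell, T and NK cell, and HIF and glycolysis lists were kept in all 15 other fits with the preset correlation. Endothelial cells (median −0.04) and BMP and TGF-beta signalling (median −0.04) gave camera adjusted p of 1 and 0.57. Both were among the lists that passed the mixed test (fry mixed adjusted p = 0.018 and 1.5e-05), so changes in either direction are not excluded. Adjusted over the list alone, 1 BMP and TGF-beta member fell and 0 endothelial members passed. The remaining fixed genes, n = 4 and 4, did not pass: Flt1 0.25, Vegfa −0.16, the nitric oxide synthase Nos3 0.24, the BMP receptor Bmpr2 −0.20, the muscle actin Acta2 0.32, Kit −0.67, Pdgfrb 0.12, Slc2a1 0.22 and Alas2 0.62. Of these, the difference of Pdgfrb turned to −0.19 and that of Vegfa to 0.06 without normoxia arrays 1 and 2. Cyp1a1, a xenobiotic-metabolising enzyme, was at least 2.07-fold higher in normoxia (6.77 ± 0.69) than in hypoxia, where it was at background (4.66 ± 0.80); its limma adjusted p was 0.214 over all genes, although the arrays did not overlap and it fell adjusted over the list alone.

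By the median difference of a list, hypoxia with SU5416 differed from normoxia most strongly in the targets of the aryl hydrocarbon receptor. This receptor is the sensor that switches on xenobiotic metabolism. Cyp1a1 rose 69.6-fold (12.89 ± 0.04 SD, n = 3, against 6.77 ± 0.69, n = 4) and Cyp1b1 10.8-fold (12.47 ± 0.09 against 9.04 ± 0.28). The receptor's repressor Ahrr rose at least 15.4-fold, the quinone reductase Nqo1 2.44-fold and Tiparp 2.52-fold. Ms4a7, a membrane protein of macrophages, rose at least 13.3-fold from background (9.45 ± 0.85 against 4.92 ± 0.35). Among the called genes that fell were Apln, the apelin peptide made by endothelial tip cells, 2.27-fold (10.19 ± 0.32 against 11.38 ± 0.13), Smad6, an inhibitor of BMP signalling induced by flow, 2.18-fold (10.44 ± 0.13 against 11.56 ± 0.18), and Spns2, the endothelial exporter of sphingosine-1-phosphate, 1.91-fold (10.39 ± 0.26 against 11.32 ± 0.07).

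In all, 19 probe sets were called (limma, 11 higher and 8 lower, 15 of them naming a single gene), with 3845 at an unadjusted p under 0.05 against 1552 by chance. The arrays of both groups did not overlap for 3697 (11.9%, against 5.71% by chance). The adjusted p was 3.83e-05 for Cyp1b1, 0.000874 for Cyp1a1, 0.00242 for Nqo1, 0.00263 for Ms4a7, 0.0131 for Tiparp, 0.0276 for Smad6, and 0.0488 for Ahrr, Apln and Spns2. The protease inhibitor Cst6 rose 1.96-fold (8.75 ± 0.22 against 7.78 ± 0.18, adjusted p = 0.0488), Ccdc3, a secreted protein of endothelium and fat, fell 1.73-fold (8.89 ± 0.07 against 9.68 ± 0.11, adjusted p = 0.0362), and the uroplakin Upk1a was at least 1.39-fold lower, its mean with SU5416 being at background. Only 1 of the 4 Smad6 probe sets was called; the others differed by −0.59, 0.34 and 0.11.

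Cyp1a1, Ms4a7 and Cyp1b1 kept their calls in all alternatives that tested them, and Nqo1 in 20 of 22. Tiparp kept its call in 17 of 22, Ahrr in 10 of 21 and Upk1a in 6 of 21. Smad6 kept it in 9, Ccdc3 in 7, Cst6 in 6, and Apln and Spns2 in 5 of 22. None changed direction, which leaving out arrays could not have brought about, since the arrays of these genes did not overlap. The highest adjusted p among these fits was 0.234, for Apln. The other called probe sets with names, outside the naming rule and chosen after their values were seen, were Slc6a17 (6.80 ± 0.10 against 5.69 ± 0.28, the normoxia mean at background, adjusted p = 0.0488) and a probe set each of Mybpc2 and Cdh1 with means below background in both groups. The brighter Cdh1 probe set differed by −0.11 (adjusted p = 0.821).

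Fewer or more probe sets passed under other settings: 43 after quantile normalization, 145 with the trend and robust options, 32 with array quality weights, 8 with only the arrays of these groups, and 366 by SAM (185 higher, 181 lower, an estimated 23.2% false). With the dimmer probe sets left out, 214 passed (106 higher, 108 lower) of 15521 tested. Without normoxia arrays 1 and 2, chosen after seeing the data, 25 were called (17 higher, 8 lower), 7 of them shared with the 19. Leaving out another pair of normoxia arrays gave 13 to 68, the 68 without arrays 3 and 4. Without hypoxia array 4 there were 38 calls, without hypoxia array 1 there were 11, without normoxia array 1 there were 12, without SU5416 array 1 there were 9, and without normoxia array 4 or hypoxia array 3 there were 8.

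**Figure D2:**
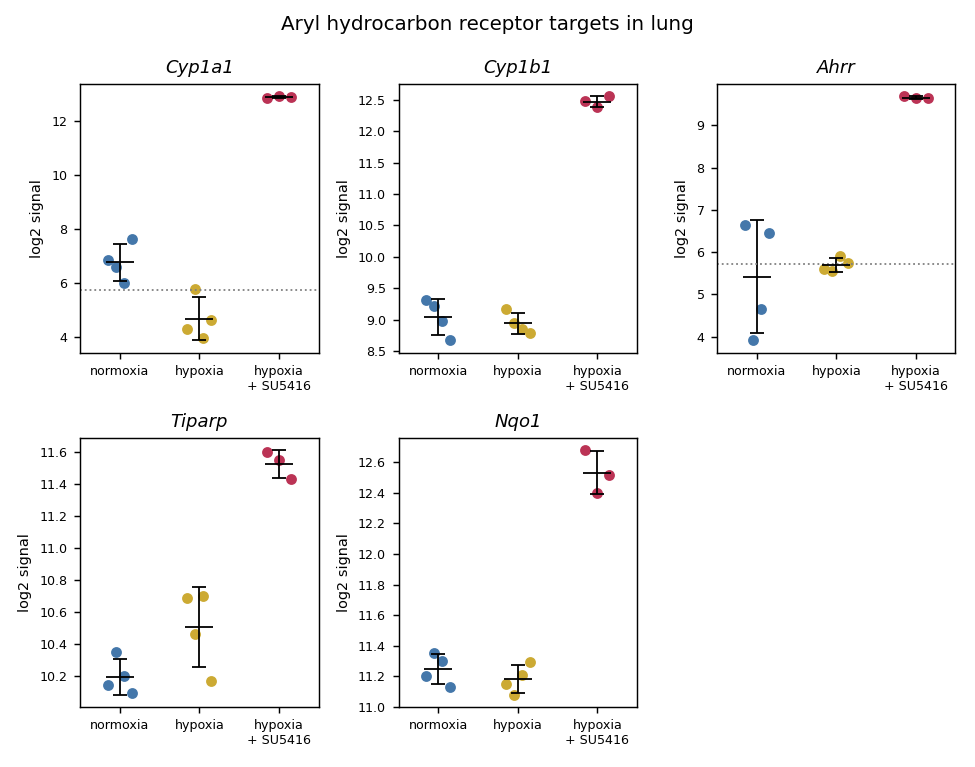
Signal (log2) of aryl hydrocarbon receptor targets on each array by group, with group means. Cyp1a1 averages 12.89 with SU5416, 6.77 in normoxia and 4.66 in hypoxia, and Cyp1b1 12.47, 9.04 and 8.94.

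As sets, 13 of 33 lists passed in hypoxia with SU5416 against normoxia, 11 up and 2 down; 1 of the 13, the aryl hydrocarbon receptor targets, passed with an estimated correlation. The same list alone passed fry, while 18 lists passed the mixed test. The median of these targets was 1.29 (7 of 9 higher, camera adjusted p = 5.7e-09; adjusted p = 0.006 with an estimated correlation), with 5 risen over all genes and 6 adjusted over the list alone. Extracellular matrix genes had a median of 0.38 (31 of 33 higher, adjusted p = 5.5e-09; adjusted p = 0.39 with an estimated correlation). No matrix gene passed over all genes, and 4 rose adjusted over the list alone: the endostatin collagen Col18a1 (2.25-fold), fibronectin Fn1 (1.38-fold), Timp1 (2.03-fold) and versican Vcan (1.76-fold). Contractile genes of smooth muscle had a median of 0.35 (14 of 18 higher, adjusted p = 1e-05; adjusted p = 0.44 with an estimated correlation). None passed over all genes; adjusted over the list alone, 9 rose, among them Actg2 (2.24-fold, SE of the log2 difference 0.24), Tpm2 (2.06-fold, SE 0.22) and desmin, Des (1.85-fold, SE 0.20), and Synpo2 fell (−0.39, SE 0.10) while its other 3 probe sets differed by 0.24, 0.05 and 0.31.

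Cholesterol synthesis genes were higher in 14 of 14 (median 0.48, camera adjusted p = 6.5e-08; adjusted p = 0.39 with an estimated correlation), with 0 past over all genes and 6 adjusted over the list alone, among them Acat2 at 0.76, Mvd at 0.64, Sqle at 0.94 and Dhcr7 at 0.51. Cell cycle genes had a median of 0.32 (28 of 30 higher, adjusted p = 9.3e-06; adjusted p = 0.44 with an estimated correlation), with Mcm6 at 0.39, Tk1 at 0.46 and Kif11 at 0.42, and no member past either adjustment. Mitochondrial respiration genes were higher in 24 of 26 (median 0.17, adjusted p = 5.4e-05; adjusted p = 0.44 with an estimated correlation), with Cyc1 at 0.49, Sdhb at 0.49, Ndufs3 at 0.29 and Sdhd at 0.25 and again no member past either adjustment. HIF targets and glycolysis genes had a median of 0.15 (21 of 29 higher, adjusted p = 0.00097; adjusted p = 0.39 with an estimated correlation). Ldha, Eno1, Aldoa and Bnip3 rose adjusted over the list alone, by 0.58, 0.66, 0.47 and 0.82, and 0 over all genes. In normoxia Eno1 was lower on array 1 (10.67) than on the others (11.28 to 11.33), which widens its difference. For glucocorticoid targets the median was 0.45 (9 of 11 higher, adjusted p = 0.0096; adjusted p = 0.44 with an estimated correlation), with Mt2A at 0.73, Errfi1 at 0.71, Cebpd at 0.68 and Sgk1 at 0.59, none past either adjustment. Their call was lost without normoxia array 3.

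Among immune and stromal lists, macrophage and monocyte genes had a median of 0.28 (15 of 20 higher, camera adjusted p = 0.00097; adjusted p = 0.44 with an estimated correlation). The complement genes C1qa, C1qb and C1qc were 2.58-fold, 3.37-fold and 3.08-fold higher (limma adjusted p = 0.0555, 0.113 and 0.0555), and they were among 6 that rose adjusted over the list alone, while the macrophage receptor Adgre1 fell 1.83-fold adjusted over the list alone. This list lost its call without normoxia arrays 1 and 2. In normoxia all 3 C1q genes were lowest on these arrays, which widens the folds given. C1qb, for example, was 7.49 and 8.02 there, against 8.97 and 9.17 on normoxia arrays 3 and 4. Inflammatory mediators had a median of 0.09 and a mean of 0.32 (19 of 28 higher, adjusted p = 0.015; adjusted p = 0.39 with an estimated correlation). The chemokines Ccl21 (0.86) and Cxcl12 (0.62) and the decoy receptor Il1r2 (at least 2.5-fold) rose adjusted over the list alone, and Ptgs2 stood at 1.15. Fibroblast genes had a median of 0.25 (11 of 14 higher, adjusted p = 0.026; adjusted p = 0.39 with an estimated correlation), of which Thy1 (0.81) rose adjusted over the list alone and Lum differed by 0.85, Mfap5 by 0.29 and Fgf10 by at least 1.38-fold. No member of these 3 lists passed over all genes. B and plasma cell genes were lower (median −0.45, 8 of 11 lower, adjusted p = 0.0021; adjusted p = 0.39 with an estimated correlation), and Bank1 (−1.43), Jchain (−1.10), Ms4a1 (−0.45) and Mzb1 (−0.68) were among 5 that fell adjusted over the list alone. T and NK cell genes were lower in 18 of 20 (median −0.28, adjusted p = 0.0028; adjusted p = 0.44 with an estimated correlation), of which Eomes fell adjusted over the list alone on 1 probe set (7.29 ± 0.26 to background), its other probe set differing by −0.79, and Klrd1 differed by −0.73, Cd2 by −0.83 and Cd247 by −0.34. No member of either lymphocyte list passed over all genes. The T and NK cell call was lost without SU5416 array 1. The fibroblast call was kept in 10 and the inflammatory call in 11 of 15 other fits, and both were lost without normoxia array 1, without normoxia array 2 and without both.

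The BMP and TGF-beta list did not shift as a set (median −0.07, camera adjusted p = 0.37). Its BMP inhibitor Smad6 fell over all genes, and adjusted over the list alone Smad6, Bmp6 (−0.61, SE 0.11) and the endothelial co-receptor Eng (−0.42, SE 0.11) fell and the BMP antagonist Grem1 rose (2.12, SE 0.34, limma adjusted p = 0.0672 over all genes). Endothelial genes did not shift as a set either (median −0.12, camera adjusted p = 0.11), with members in both directions adjusted over the list alone: Nos3 rose 1.57-fold (8.14 ± 0.11 against 7.49 ± 0.07) and Kdr fell 1.41-fold (12.09 ± 0.19 against 12.58 ± 0.07), with limma adjusted p of 0.1 and 0.136 over all genes. After quantile normalization this list passed as lower. The remaining fixed genes did not pass over all genes: Edn1 0.71, Vegfa −0.52, Flt1 0.19, Bmpr2 −0.31, Acta2 0.40, Kit −0.81, Pdgfrb 0.17, Slc2a1 0.10 and Alas2 0.77, with limma adjusted p from 0.179 for Edn1 to 0.802 for Pdgfrb. Pdgfrb turned to −0.15 without normoxia arrays 1 and 2 and to −0.01 without SU5416 array 2.

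**Figure D3:**
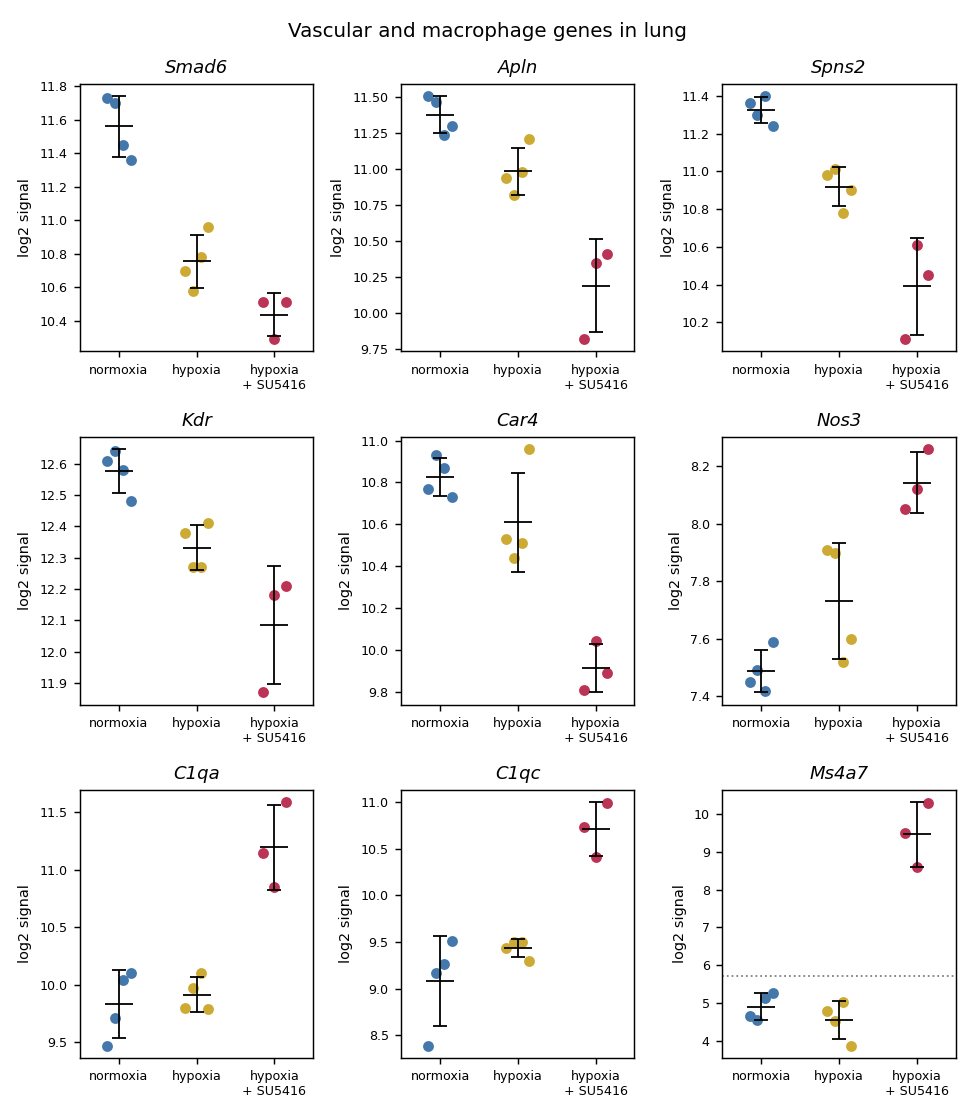
Signal (log2) of vascular and macrophage genes on each array by group, with group means. Smad6 averages 10.44 with SU5416 and 11.56 in normoxia, and C1qc 10.71 with SU5416, 9.44 in hypoxia and 9.09 in normoxia.

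Few single genes were called between hypoxia with SU5416 and hypoxia alone, among them 3 targets of the aryl hydrocarbon receptor and the macrophage gene Ms4a7. Cyp1a1 rose at least 144-fold, from background (4.66 ± 0.80 SD, n = 4) to 12.89 ± 0.04 (n = 3), Cyp1b1 11.6-fold (from 8.94 ± 0.17) and Nqo1 2.55-fold (from 11.18 ± 0.09). Ms4a7 rose at least 13.3-fold, from 4.56 ± 0.49. Nfatc2, a calcineurin-dependent transcription factor of lymphocytes and muscle, rose 2.06-fold (9.15 ± 0.04 against 8.11 ± 0.15).

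Between the hypoxic groups, 8 probe sets were called (limma, 7 higher and 1 lower), with 2319 at an unadjusted p under 0.05 against 1552 by chance. The arrays did not overlap for 3575 (11.5%, against 5.71% by chance). The adjusted p was 2.88e-05 for Cyp1b1, 7.61e-05 for Cyp1a1, 0.000923 for Nqo1 and Ms4a7, and 0.0191 for Nfatc2. Cyp1a1, Ms4a7 and Cyp1b1 kept their calls in all alternatives that tested them and Nqo1 in 21 of 22. Nfatc2 kept its call in 13 of 22, with adjusted p between 0.00303 and 0.238, and its other probe set differed by 0.15. The remaining 3, outside the naming rule and chosen after their values were seen, were an unnamed probe set (1.30), the Cdh1 probe set below background, and Opcml at 8.16 ± 0.26 with SU5416, 5.15-fold above hypoxia alone (adjusted p = 0.000251). The count was 14 after quantile normalization, 16 with trend and robust options, 24 with array quality weights and 309 by SAM (308 higher, 1 lower, an estimated 22.5% false). Without SU5416 array 3 it was 15, without normoxia array 1 it was 14, and without normoxia arrays 1 and 2, which enter this contrast only through the spread, it was 16. The 8 were among the calls of both fits that left out normoxia arrays.

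As sets, 10 of 33 lists passed in hypoxia with SU5416 against hypoxia, 9 up and 1 down. The aryl hydrocarbon receptor targets were the only list to pass with an estimated correlation and the only list to pass fry; 6 lists passed the mixed test. Their median was 1.02 (9 of 9 higher, camera adjusted p = 2.5e-17; adjusted p = 0.00051 with an estimated correlation), with 3 risen over all genes and 6 adjusted over the list alone. Tiparp, 2.03-fold higher, had a limma adjusted p of 0.0726 over all genes. Macrophage and monocyte genes had a median of 0.27 (18 of 20 higher, adjusted p = 0.00013; adjusted p = 0.44 with an estimated correlation). C1qa (2.43-fold), C1qb (2.93-fold) and C1qc (2.42-fold) were among 4 that rose adjusted over the list alone, and Adgre1 (−0.64) fell adjusted over the list alone. Inflammatory mediators had a median of 0.31 (24 of 28 higher, adjusted p = 1.2e-05; adjusted p = 0.13 with an estimated correlation). Cxcl12 (0.54), Cxcl10 (1.04) and the endothelial adhesion molecule Sele (at least 2.17-fold) rose adjusted over the list alone, although another bright probe set of Cxcl12 differed by −0.65. No member of either list passed over all genes.

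Extracellular matrix genes had a median of 0.25 (28 of 33 higher, camera adjusted p = 1.2e-05; adjusted p = 0.57 with an estimated correlation), with Timp1 at 0.99, Col18a1 at 0.74, Tnc at 0.68 and Fn1 at 0.41. Smooth muscle contractile genes were higher in 17 of 18 (median 0.23, adjusted p = 1.7e-05; adjusted p = 0.44 with an estimated correlation), with Actg2 at 0.95, Cnn1 at 0.69, Des at 0.62 and Tpm2 at 0.58. Cholesterol synthesis genes had a median of 0.22 (12 of 14 higher, adjusted p = 0.0024; adjusted p = 0.68 with an estimated correlation), with Nsdhl at 0.46, Cyp51 at 0.42, Acat2 at 0.39 and Insig1 at 0.25, a call lost without SU5416 array 3. No member of these 3 lists passed over all genes or adjusted over the list alone. Cell cycle genes were higher in 29 of 30 (median 0.28, adjusted p = 1.5e-06; adjusted p = 0.44 with an estimated correlation), with Mcm5 at 0.40, Tk1 at 0.46 and Aurka at 0.69. Of these, 0 passed over all genes and 1, Bub1b, at background in both groups, passed adjusted over the list alone.

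The remaining sets passed narrowly. Endothelial genes were lower in 19 of 26 (median −0.10, camera adjusted p = 0.044; adjusted p = 0.7 with an estimated correlation): the capillary carbonic anhydrase Car4 fell 1.62-fold adjusted over the list alone, Pecam1 differed by −0.31 and Kdr by −0.25, and Nos3 went the other way (0.41). Adipocyte genes (median 0.20, 9 of 12 higher, adjusted p = 0.044; adjusted p = 0.7 with an estimated correlation) included Ucp1, at least 1.96-fold higher and risen adjusted over the list alone, Pck1 at 0.60 and Cfd at 0.42. Neutrophil genes (median 0.55, 6 of 9 higher, adjusted p = 0.048; adjusted p = 0.44 with an estimated correlation) included Lcn2 at 1.23 and Mmp8 at 0.28. Il1r2 was at least 2.5-fold and Cxcr2 at least 1.36-fold higher, and no member was past either adjustment. No member of these 3 lists passed over all genes, and their calls were kept in 11, 7 and 8 of 15 other fits. Of the fixed genes, Edn1 differed by 0.41, Vegfa by −0.36, Flt1 by −0.06, Bmpr2 by −0.11, Acta2 by 0.08, Kit by −0.13, Pdgfrb by 0.05, Slc2a1 by −0.12 and Alas2 by 0.14, none past the threshold (limma adjusted p from 0.672 to 0.978). The signs of Flt1, Bmpr2, Kit, Pdgfrb and Alas2 turned when single arrays were left out.

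**Figure D4:**
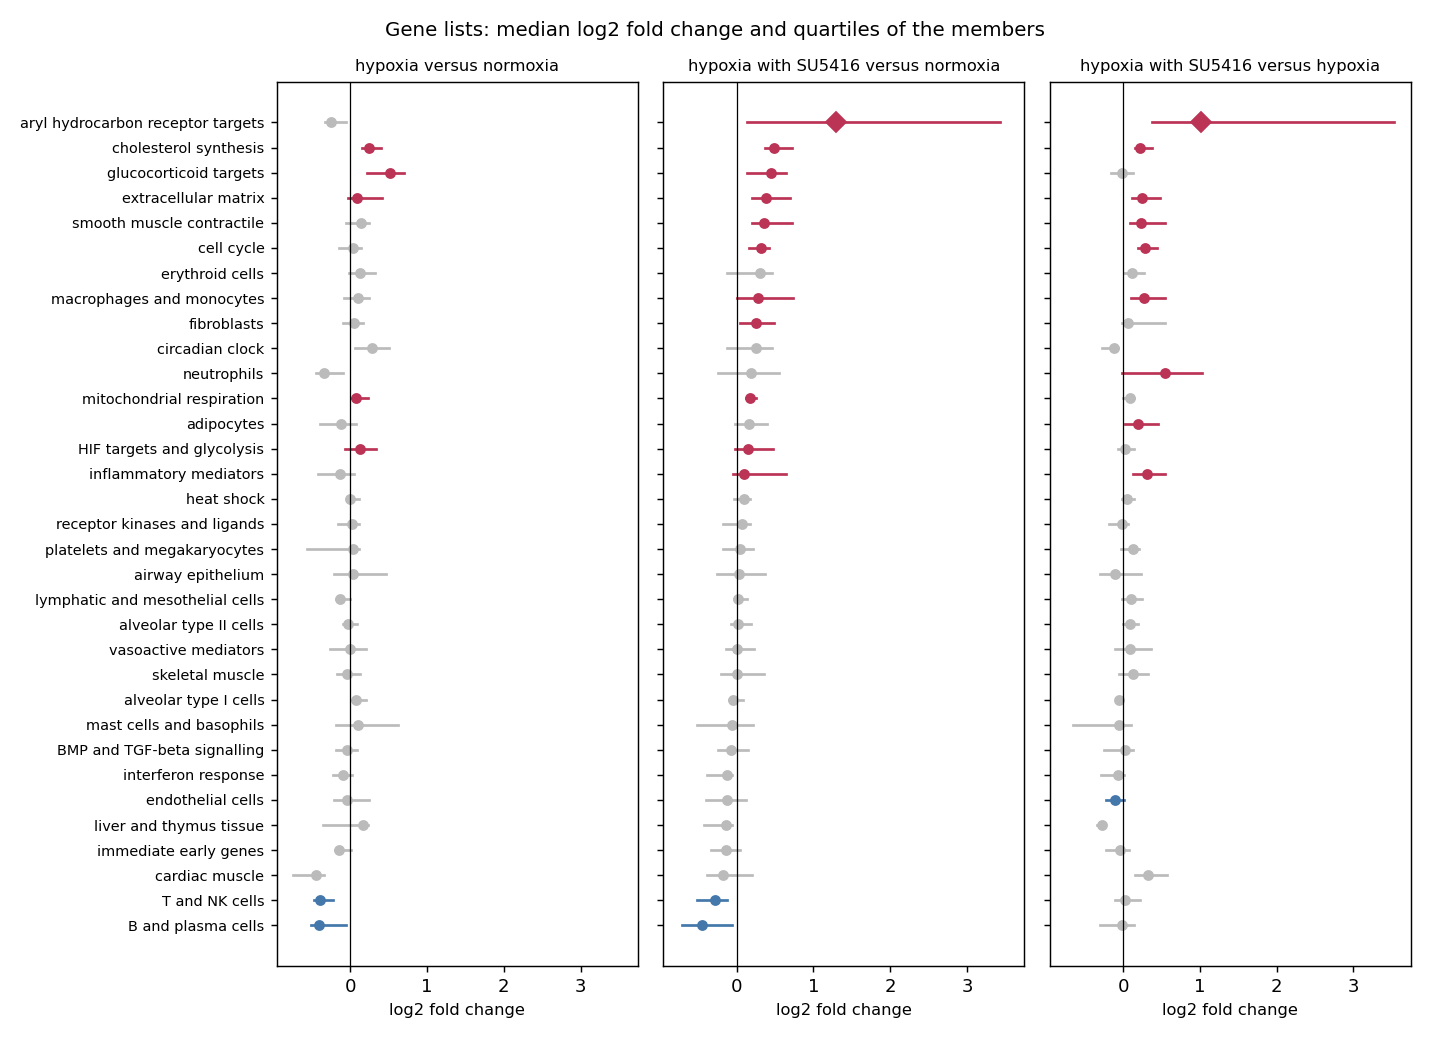
Median log2 difference of each gene list in the 3 comparisons. The aryl hydrocarbon receptor targets lie at 1.29 and 1.02 with SU5416 against normoxia and against hypoxia, and at −0.25 in hypoxia against normoxia.

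Markers of the airway and alveolar epithelium gave no shift as sets in any comparison: camera adjusted p was 0.85, 0.48 and 0.3 for alveolar type II cells, 0.39, 0.9 and 0.52 for alveolar type I cells, and 0.76, 0.98 and 0.58 for airway epithelium, in the order hypoxia against normoxia, hypoxia with SU5416 against normoxia, and hypoxia with SU5416 against hypoxia. Without normoxia arrays 1 and 2, chosen after seeing the data, the alveolar type I list passed as higher in both comparisons with normoxia.

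The differences of both hypoxic groups from normoxia share the same 4 normoxia arrays. A single probe set, that of Slc6a17, was called in both and in the same direction. Lists of these sizes drawn independently would share 0.00035 higher and 0.00026 lower. Across the 31042 probe sets, which are not independent replicates, the log2 differences had a correlation of 0.56 and a covariance of 0.0951. Unchanged groups simulated against shared controls gave 0.55 and 0.0694, so the shared arrays alone reach this correlation, and the covariance exceeded theirs by 0.0257. With the normoxia arrays split so that each comparison had its own pair, the 6 splits gave correlations from −0.09 to 0.23 (mean 0.12), covariances from −0.025 to 0.0498 (mean 0.0265) and 0 to 1 shared calls.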

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

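The count of other splits of the arrays was planned; the tests on the aryl hydrocarbon receptor targets, on the number of calls in hypoxia and on the C1q genes were chosen after those results were seen.

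In the groups of 4 arrays, 12 of 284 tests (142 measures in the normoxia and hypoxia groups) found 1 array far from the other 3; chance flags about 1 in 20. Hypoxia array 4 stood apart for Grem1 (6.03, others 7.19 to 7.41), Ptgs2 (7.22, others 8.51 to 8.67), Nfatc2 (8.33, others 8.03 to 8.04) and the mean of the B and plasma cell list (9, others 8.57 to 8.62). Hypoxia array 3 did so for C1qb (8.29, others 8.69 to 8.75) and Sqle (9.47, others 9.24 to 9.27), and hypoxia array 2 for Adgre1 (8.38, others 8.12 to 8.16) and the adipocyte list mean (8.03, others 7.62 to 7.68). In normoxia, array 1 was low for Eno1 (10.67, others 11.28 to 11.33) and the mitochondrial respiration list mean (10.6, others 10.94 to 11.01), array 3 for Bmp6 (11.73, others 11.88 to 11.90) and array 4 for Des (9.69, others 10.32 to 10.38). Being no more frequent than chance gives, these were not weighed further.

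Each comparison was repeated over the 35 splits of its arrays into groups of the same sizes. For hypoxia against normoxia, 4 splits called at least as many probe sets as the real 2, so chance is not excluded; the highest other split called 58, many times the real count. That split set hypoxia arrays 1 and 4 with normoxia arrays 3 and 4 against the rest, which parts normoxia arrays 1 and 2 from 3 and 4 and points to a structure of the samples other than the groups. For hypoxia with SU5416, only the real split, 1 of 35, called as many. It called 19 against normoxia (highest other 3) and 8 against hypoxia (highest other 2). A share of 1 in 35 is the smallest these splits can give, and both comparisons use the same SU5416 arrays. Chance is therefore less likely for these calls but not excluded. For the number of gene lists passed, 13 splits gave as many as the real 7 in hypoxia against normoxia (highest other 14), 5 as many as the real 13 in hypoxia with SU5416 against normoxia (highest other 15), and 5 as many as the real 10 against hypoxia (highest other 13). Chance is therefore not excluded for any of the 3 numbers of lists.

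The aryl hydrocarbon receptor targets were higher with SU5416 than in hypoxia alone, with a median of 1.02. With the beta-actin gap as a covariate the median was 1.02, and Cyp1a1, Cyp1b1 and Nqo1 kept their calls. But the gaps of the SU5416 arrays (0.56 to 0.67) lie below those of all hypoxia arrays (0.68 to 0.87). The covariate therefore cannot decide on the gap in this comparison. After quantile normalization the median was 1.03. The medians of the arrays compared, 7.802 to 7.949 log2, lie too close for scaling to give such a rise. Quantile normalization thus could not have removed it. For 5 of the 9 members, Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1, all 3 SU5416 arrays lay above all 8 others. Those others include normoxia arrays 3 and 4, whose gaps (0.51 and 0.6) are near those with SU5416. For these 5 members this argues against the gap as the whole cause. All 5 had already been called against normoxia, and 3 of them (Cyp1a1, Cyp1b1 and Nqo1) against hypoxia alone, so their separation adds no test of a response to SU5416. Such a response, whether to SU5416 itself, its vehicle or a secondary effect, stays open.

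Hypoxia alone gave few calls. Leaving out normoxia arrays 1 and 2 raised the number to 99, whereas leaving out any other pair of normoxia arrays gave 3 to 10. The larger beta-actin gap of this pair is therefore a candidate explanation for the low count. However, the gaps of normoxia arrays 3 and 4 (0.51 and 0.6) lie below those of all hypoxia arrays (0.68 to 0.87). The 99 calls thus cannot be told apart from a difference in the gap. The median SD of the remaining pair, 0.148, was below the 0.204 to 0.274 of the other pairs. With the gap as a covariate there were 4 calls, so a straight-line correction did not bring the same gain, and another difference that these arrays share stays open. No biological explanation was tested, since the labels name none that separates them.

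The C1q genes were higher with SU5416 than in hypoxia alone, by a mean of 1.37 (SE 0.26), against 0.19 (SE 0.15) for the other 17 macrophage and monocyte markers. The 3 C1q genes were chosen as those that rose most, so the markers not chosen lie lower in part by that choice. The median shift of those other markers was 0.23 (SD between markers 0.33, from −0.64 to 0.68). Whether more macrophages of the same kind would raise all markers alike was not tested either. The comparison thus cannot decide on more such macrophages, which stay open as the whole cause or a part of it. With the beta-actin gap as a covariate the C1q shift was 1.25 (SE 0.12). The gaps with SU5416 (0.56 to 0.67) lie below all those in hypoxia (0.68 to 0.87), so the covariate cannot decide how far the gap contributes. All 3 C1q genes stood lower on normoxia arrays 3 and 4, with gaps of 0.51 and 0.6, than on the SU5416 arrays. C1qb, for example, was 8.97 and 9.17 there against 9.98 to 10.31. A macrophage population of another kind, or a higher output of C1q per cell, stays open too.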

How the results depend on the processing

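All alternatives were planned except the fits without normoxia arrays 1 and 2 and with the beta-actin gap as a covariate, which were chosen after seeing the data. For the named genes called, 247 refitted values stayed past the threshold and 121 fell short of it in the same direction. No called gene reversed, but their arrays did not overlap between the groups. Leaving out or weighting arrays could therefore not have turned the sign. For named genes not called, counted together with the median of the aryl hydrocarbon receptor targets in hypoxia against normoxia, 3100 values stayed as they were, 92 passed and 17 changed sign. Calls numbered 2 (hypoxia against normoxia), 19 (hypoxia with SU5416 against normoxia) and 8 (hypoxia with SU5416 against hypoxia). In that order they were 1, 43 and 14 after quantile normalization, 1, 145 and 16 with trend and robust options, and 584, 366 and 309 by SAM. Of the first 2 comparisons, leaving out dimmer probe sets gave 0 (1824 at an unadjusted p under 0.05) and 214, the interquartile filter 1 and 10, and fitting only the groups compared 1 and 8. Centring on the median gave 1 in the first; array quality weights gave 32 and 24 in the last 2. A threshold of 0.1 gave 108 and 18 there. Without normoxia arrays 1 and 2 the first and last had 99 and 16 calls, and with the gap covariate 4 and 18. Leaving out each array in turn gave 1 to 14, 8 to 38 and 7 to 15. The cause was not tested, except that fewer arrays or probe sets enter some of these fits by construction.

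Replicate numbers did not pair the arrays: same-number correlations between groups ran from −0.28 to 0.34. With the number as a block, calls were 1, 6 and 6.

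Gene lists passed numbered 7, 13 and 10, and 0, 1 and 1 with an estimated correlation; without each array in turn, 5 to 8, 11 to 16 and 8 to 12. The median of the aryl hydrocarbon receptor targets ranged from 1.21 to 1.32 against normoxia and from 0.91 to 1.09 against hypoxia without each array in turn. The correlation of both differences from normoxia, 0.56, was 0.12 with split controls and 0.62 without dimmer probe sets. Signal limits the dimmest genes: 18.8% of probe sets averaged below background.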

Other observations

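The genes of this part were chosen after their values were seen, and no explanation is offered for them. With probe sets of a mean below the median of all left out, which leaves 15521, hypoxia with SU5416 against normoxia gave 214 calls (n = 3 and 4, limma), including genes that were not among the 19 of all probe sets. Of 24 endothelial list members measured there, 2 fell and 0 rose: the capillary enzyme Car4 by 0.91 on the log2 scale (adjusted p = 0.0106) and Kdr by 0.49 (adjusted p = 0.0437). Outside that list, called genes that fell include the serotonin transporter Slc6a4 by 1.00 (adjusted p = 0.0268), the prostaglandin-degrading enzyme Hpgd by 1.55 (adjusted p = 0.0333) and the clotting inhibitor Tfpi by 0.75. The prostacyclin synthase Ptgis rose (0.83, adjusted p = 0.0239). Among macrophage genes, C1qa (1.37) and C1qc (1.62) rose with an adjusted p of 0.00995 each and C1qb (1.75) with 0.0333, Chi3l1 rose (0.99), and Adgre1 fell by 0.87. In normoxia the C1q genes were lowest on arrays 1 and 2, which widens their differences.

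Of 33 extracellular matrix genes, 2 rose (Col18a1 at 1.17 and Fn1 at 0.47), and of 16 contractile genes, 3 rose (Actg2 at 1.16, Tpm2 at 1.04 and Des at 0.89). Against hypoxia alone the same filter gave 12 calls, among them Tiparp (1.02), C1qa (1.28), the scavenger receptor Stab1 (0.77), Clic2 (0.85), Cytl1 (0.74) and Ccdc3, which fell by 0.71. Hypoxia against normoxia gave 0 calls with this filter in limma, 1824 probe sets at an unadjusted p under 0.05, and 584 calls by SAM on all probe sets.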
